A study of Mus musculus with 4 samples.

How the data were processed

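RNA of LL2 cells gave 4 libraries, 2 from cells treated with lactic acid at 20 mM for 24 h and 2 with PBS for 24 h. Per the labels' protocols, RNA was extracted with TRIzol, polyadenylated RNA was selected, and libraries were made with a NEBNext Ultra kit, which does not mark the strand of the transcript. Per the labels, the libraries were read in pairs of 150 bases on an Illumina NovaSeq. Control libraries carry the letters NS in their names while the labels give their treatment as PBS, and the labels' treatment was followed.

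The count table holds whole-number read counts per gene for each library, as deposited, with no scaling. Per the submitters' processing notes, CASAVA, HISAT2 2.0.5, featureCounts 1.5.0-p3, StringTie 1.3.3b and DESeq2 1.16.1 were used with the builds GRCm38.p6 and mm10, and the notes assign no step to any of them. The treatment of strand, of reads that map to several places and of overlapping genes is not stated. The second table gives FPKM values that the authors deposited for the same genes and libraries. Dividing each count by the gene length of the table and by the FPKM gave 1 constant per library for all genes above 0, within a relative tolerance of 1e-06. That constant was 0.982, 0.985, 1.025 and 1.022 times the library's total count, so the FPKM of the authors carry a scaling between libraries. Gene positions are those of the deposited tables, on GRCm38.

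Depth was 15501006 to 17409990 counts per library. At that depth 3 counts correspond to 0.175 to 0.190 CPM in a library, and this limit covers counting error only, since PCR copies cannot be told from independent molecules here. Chac1 rests on 22 to 92 reads a library and its change has a standard error of 0.28 on the log2 scale, while Scd2, with 5776 to 19621 reads a library, reaches 0.03.

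Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 13922 of 54532, and library sizes were scaled by TMM with factors of 0.983 to 1.017. A quasi-likelihood model with robust settings was fitted to the 4 libraries with the group as the only term, and lactic acid was compared with PBS by glmQLFTest, two-sided, with Benjamini-Hochberg adjustment over all genes kept and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM use the TMM-scaled library sizes.

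A collection of 34 gene lists from textbook knowledge was written before the data were examined, as were the design and the rule for named genes. Of these, 32 had at least 3 genes kept and were tested with limma 3.58.1's camera on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the 32 lists. The lists of lymphocyte and endothelial markers were too low in counts to test. Beside each test stand the numbers of members past the edgeR threshold over all genes and those past it when only the members of that list were adjusted. Lists share genes, and the numbers of the stress response and ferroptosis lists are not independent of each other.

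The rule for named genes took Chac1, the 10 genes each way with the largest log2 fold change among those past the threshold with a mean of at least 10 CPM, separate groups and a gene symbol that is not a clone or model name, the 4 members of each list with the smallest p, a fixed set of 20 genes of ferroptosis, stress, lactate handling and acid sensing, and the 5 most abundant genes. Of the genes this rule took, 4 are not reported here.

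Genes that share reads with near-identical copies were found by comparing the longest GENCODE transcript of each gene with those of all others (blastn 2.17.0, at least 98% identity over at least 300 bases). Of the genes tested, 1073 had such a copy. Where another annotated gene overlaps a named gene and holds at least 10% as many reads, the partner is given, since reads of overlapping genes cannot be separated without strand.

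The procedure was tested on simulated counts with the means and library sizes of these data (13658 genes). The edgeR test called 30%, 64%, 82% and 96% of the genes changed by 0.25, 0.5, 1 and 2 on the log2 scale. Each size had 50 genes, and every changed gene called had the right sign. Beside these 15, 32, 41 and 48 genes, the test called 17 of 13458 unchanged genes. Unchanged genes were thus a larger share of the calls than the Benjamini-Hochberg threshold aims for. In the data 49.0% of the genes tested were called, far more than were changed in the simulation. The simulated rates therefore need not hold for the data. In simulated lists of 25 genes, camera with the preset correlation passed 20 of 20 lists shifted by 0.4 and 2 of 20 unshifted lists. With an estimated correlation it passed 0 of 20 shifted lists, so at 2 residual degrees of freedom that form of the test has little power. All simulated genes were drawn independently, and the changes of single genes had a spread of 0.4 on the log2 scale. Lists of correlated genes were not simulated, so these rates need not hold for them.

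Alternatives were DESeq2 size factors and upper-quartile scaling, no filter and a filter of 1 CPM in 2 libraries, DESeq2 1.42.0's Wald test, limma-voom, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), the replicate number as a block, each library left out in turn, stricter thresholds of size, and for the lists camera with an estimated correlation, fry, and camera without shared genes. Removing a trend on GC content, leaving out genes with near-identical copies, and camera with an estimated correlation without shared genes were added after seeing the data. No reads were aligned here, and splicing was not analysed here.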

Results

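Gene expression was measured by bulk RNA sequencing of polyadenylated RNA in LL2 cells, a mouse tumour line established from a Lewis lung carcinoma. One group received lactic acid, the acidic end product of glycolysis, at 20 mM for 24 h. The control group received the same volume of PBS, a buffered saline, for 24 h. Each group held 2 libraries that the labels call biological replicates, and the labels do not say whether these were separate cultures. Counts summed to 16164237 and 17409990 in the PBS libraries and to 15501006 and 16331584 in the lactic acid libraries. Between 20526 and 21230 genes had at least 1 count in a library, and 13922 of the 54532 genes in the table were abundant enough to test. The 10 most abundant genes took 5.11% to 5.19% of the counts, and transcripts of the mitochondrial genome 2.25% to 2.29%. Abundances are given in CPM, counts scaled to the size of each library, as the mean ± SD of the 2 libraries of a group, and fold changes are lactic acid relative to PBS.

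The series title links lactic acid to Chac1 and to ferroptosis, an iron-dependent cell death driven by lipid peroxidation, so the comparison asks what lactic acid changed in these cells, with Chac1 first. Chac1, which encodes an enzyme that degrades glutathione, was higher with lactic acid (2.59-fold), as were the cystine transporter gene Slc7a11 (3.58-fold) and Txnip (5.72-fold), whose product restrains glucose uptake. Neither the list of genes that protect against ferroptosis nor that of its drivers and markers passed (camera adjusted p = 0.278 and 0.697). Among the 32 gene lists tested, targets of p53 and of NRF2, genes of the integrated stress response, cytokine genes, immediate early genes and cytosolic ribosomal protein genes rose, together with the 3 listed targets of the transcription factor MondoA. Genes of DNA replication, of ribosome assembly and of cholesterol synthesis fell. None of these lists passed camera with a correlation between genes estimated from these libraries (adjusted p = 0.289 to 0.292). The estimates were negative for ribosome assembly, stress response, cytokine, cholesterol, immediate early and MondoA lists (-0.295 to -0.012). They were 0.013 to 0.033 for the lists of DNA replication, p53, NRF2 and ribosomal proteins. With 2 residual degrees of freedom that form passed 0 of 20 shifted lists in simulated data. It therefore cannot decide whether correlation between genes undercuts the calls.

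Altogether 6822 genes, 49.0% of those tested, passed the edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p below 0.05. Of these, 3445 were higher and 3377 lower with lactic acid. The scaling places the typical gene near no change (median log2 fold change of all genes tested 0.0073). Higher and lower are therefore relative to the other genes, and a shift of all RNA alike would not show. Most changes were small, with a median of 1.3-fold among the genes past the threshold. A change of at least 2-fold was reached by 635 higher and 228 lower genes. The libraries of a group correlated at 0.993 and 0.992 (Pearson's r of log2 CPM across genes, which are not independent replicates), against 0.977 between groups. In 72.3% of the genes tested both lactic acid libraries lay on the same side of both PBS libraries, where chance gives 33.3%. A DESeq2 Wald test on the same genes called fewer, 2251 higher and 2494 lower. With 2 libraries against 2, a single gene tested alone by exact permutation could reach no two-sided p below 0.333, so the calls rest on the spread shared between genes in the model.

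The gene with the largest rise among abundant genes was Rgs16, a regulator that shortens G protein signalling, at 60.8 ± 1.25 CPM with lactic acid and 5.15 ± 0.0221 CPM with PBS (11.8-fold, log2 fold change 3.56, SE 0.10). Txnip followed at 152 ± 6.65 against 26.6 ± 1.01 CPM (log2 fold change 2.52, SE 0.06). Lif, a cytokine of the interleukin-6 family, rose 4.46-fold, and Plau, the urokinase protease, reached 163 ± 1.82 against 36.6 ± 0.572 CPM (4.45-fold). The membrane metalloproteinases Adam19 and Adam8 rose 5.26-fold and 3.89-fold. Ccbe1, a secreted protein needed for lymphatic vessel growth, rose 4.23-fold, and Lgr6, a receptor for R-spondins, 3.96-fold. The adjusted p of these 8 genes in the edgeR quasi-likelihood test (Benjamini-Hochberg) lay between 2.22e-42 for Txnip and 6.71e-20 for Adam8.

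The steepest fall among abundant genes was that of Dpt, which encodes the matrix protein dermatopontin, at 3.15 ± 0.501 CPM with lactic acid and 21.5 ± 1.36 CPM with PBS (log2 fold change -2.77, SE 0.16). Cdc42ep2, an effector of the small GTPase Cdc42, fell by 2.02 on the log2 scale. Scd2, a desaturase that makes monounsaturated fatty acids, was the most abundant gene among the 10 and fell from 1146 ± 0.943 to 377 ± 13.9 CPM (log2 fold change -1.60, SE 0.03). Wisp1, a secreted matricellular protein (-1.58), Apcdd1, a membrane glycoprotein (-1.45), Tle2, a corepressor (-1.42), Amot, a scaffold of the Hippo pathway (-1.54), Mgst3, a microsomal glutathione transferase (-1.54), Bcl6, a transcriptional repressor (-1.47), and S100a4, a calcium-binding protein (-1.46), completed them. Adjusted p-values of these 10 genes ran from 8.32e-49 for Scd2 to 9.44e-12 for Bcl6 (edgeR quasi-likelihood, Benjamini-Hochberg).

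**Figure D1:**
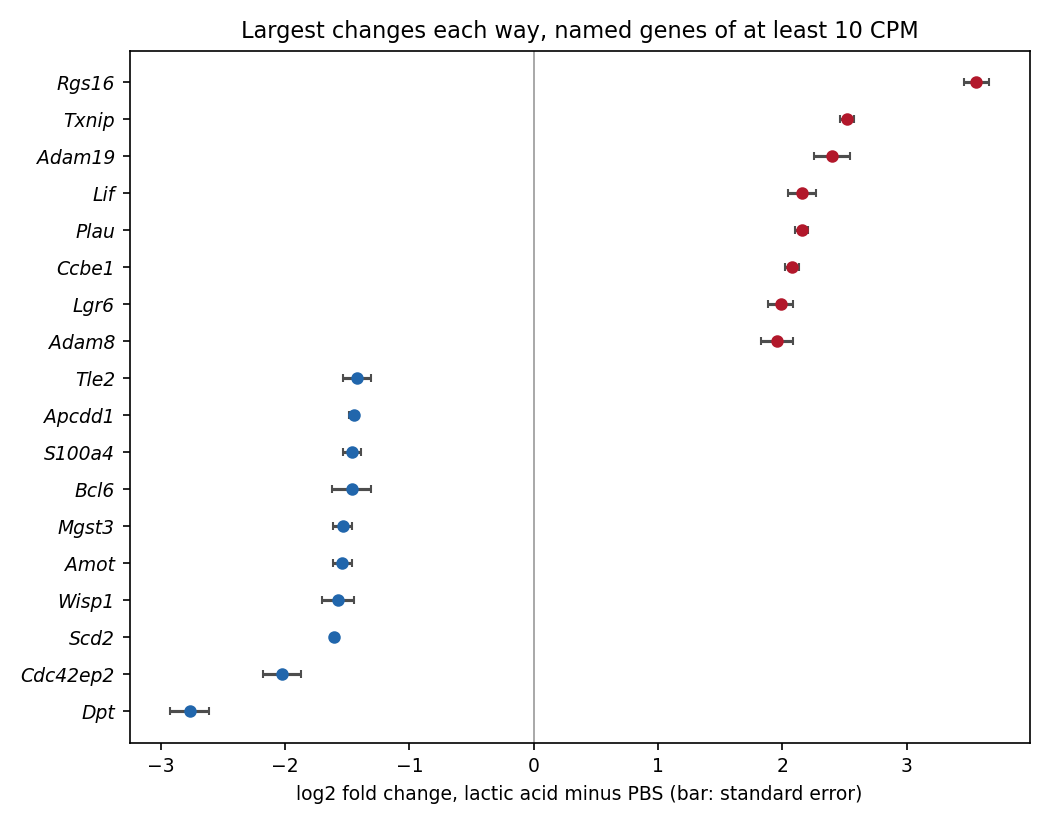
Log2 fold changes (lactic acid minus PBS, x axis) of 8 of the 10 genes with the largest rise (red) and the 10 with the largest fall (blue) among named genes with a mean of at least 10 CPM, with bars for the standard error of the edgeR fit to 2 libraries per group. Rgs16 lies at 3.56 and Dpt at -2.77.

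Chac1 lies on chromosome 2 at 119351229 to 119354381 on the plus strand of GRCm38 (gene ENSMUSG00000027313, protein-coding). It was a gene of low abundance, with 22 and 39 counts in the PBS libraries and 63 and 92 in the lactic acid libraries. Its level was 4.78 ± 1.1 CPM with lactic acid and 1.83 ± 0.629 CPM with PBS, a log2 fold change of 1.37 (SE 0.28) with an adjusted p of 3.20e-05 in the edgeR quasi-likelihood test (Benjamini-Hochberg). Both lactic acid libraries lay above both PBS libraries. Among the fixed gene lists, Chac1 belonged to those of the integrated stress response, of glutathione metabolism and of ferroptosis drivers.

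In the integrated stress response list, 26 of the 39 genes tested were higher with lactic acid, 7 lower and 6 did not pass (27 higher and 7 lower adjusted over the list alone). The list rose by camera, a competitive test against all other genes (Benjamini-Hochberg adjusted p = 7.64e-04). It did not pass with an estimated correlation (camera adjusted p = 0.289). The proline synthesis genes Pycr1 and Aldh18a1 rose 3.68-fold and 1.70-fold, and Asns, the asparagine synthetase gene, rose from 142 ± 2.83 to 239 ± 2.25 CPM (log2 fold change 0.75, SE 0.04). Trib3, a pseudokinase induced under stress, rose 2.11-fold. Atf3, a stress-induced transcription factor, rose 1.97-fold with an adjusted p of 0.00129 (edgeR quasi-likelihood, Benjamini-Hochberg). Without PBS replicate 2 its adjusted p was 0.0627, in a range of 0.000178 to 0.0627 over 15 alternatives. Atf4 mRNA, which encodes the transcription factor the list is named for, was slightly lower at 222 ± 0.77 against 240 ± 10.1 CPM (log2 fold change -0.11, SE 0.04, edgeR adjusted p = 0.00683). Without PBS replicate 2 that call was lost as well, at an edgeR adjusted p of 0.240 in a range of 0.00142 to 0.240. Ddit3, which encodes the transcription factor CHOP, measured 9.87 ± 0.744 and 8.70 ± 0.343 CPM, which did not pass the test (log2 fold change 0.18, edgeR adjusted p = 0.335). It overlaps Mars on the other strand, and reads of the pair cannot be told apart without strand.

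The list of endoplasmic reticulum chaperones and degradation genes held 4 higher and 12 lower genes of 24, the same counts adjusted over the list alone, and did not pass camera (adjusted p = 0.205). Calr and Canx, chaperones of glycoprotein folding, fell by 0.45 and 0.37 on the log2 scale, Pdia3 fell by 0.23, and Pdia6, a disulfide isomerase, rose by 0.23.

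The ferroptosis lists moved in both directions. Of 23 tested genes that protect against ferroptosis, 12 were higher and 6 lower, and of 27 drivers and markers, 10 were higher and 7 lower, in each case the same counts adjusted over the list alone. Neither list passed camera (adjusted p = 0.278 and 0.697). Slc7a11, which imports cystine for glutathione synthesis, rose from 5.38 ± 0.677 to 19.3 ± 0.103 CPM (log2 fold change 1.84, SE 0.14). Txnrd1, the cytosolic thioredoxin reductase, rose 1.82-fold, and Ptgs2, the prostaglandin synthase often used as a ferroptosis marker, rose from 40.6 ± 2.60 to 138 ± 0.482 CPM (3.39-fold). Slc1a5, a glutamine transporter, rose by 0.40 on the log2 scale. Scd1, a desaturase like Scd2, fell by 0.62, Tfrc, the receptor for iron-loaded transferrin, fell by 0.52, and Trp53 fell by 0.50 on that scale. Acsl4, which loads cells with peroxidisable lipids, was at 76.4 ± 0.959 and 78.7 ± 0.277 CPM (log2 fold change -0.04, edgeR adjusted p = 0.537), and Hmox1, the heme oxygenase, at 20.4 ± 0.018 and 21.2 ± 0.950 CPM (-0.06, edgeR adjusted p = 0.679). Gpx4, the peroxidase that reduces lipid peroxides, stood at 183 ± 5.66 with lactic acid and 198 ± 6.59 CPM with PBS (log2 fold change -0.11, edgeR adjusted p = 0.0161). That call was lost in 6 of 14 alternatives, among them the fits without PBS replicate 1 (edgeR adjusted p = 0.234) and without lactic acid replicate 2 (0.169), with a range of 6.86e-05 to 0.234, and Gpx4 shares sequence with a near-identical copy.

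**Figure D2:**
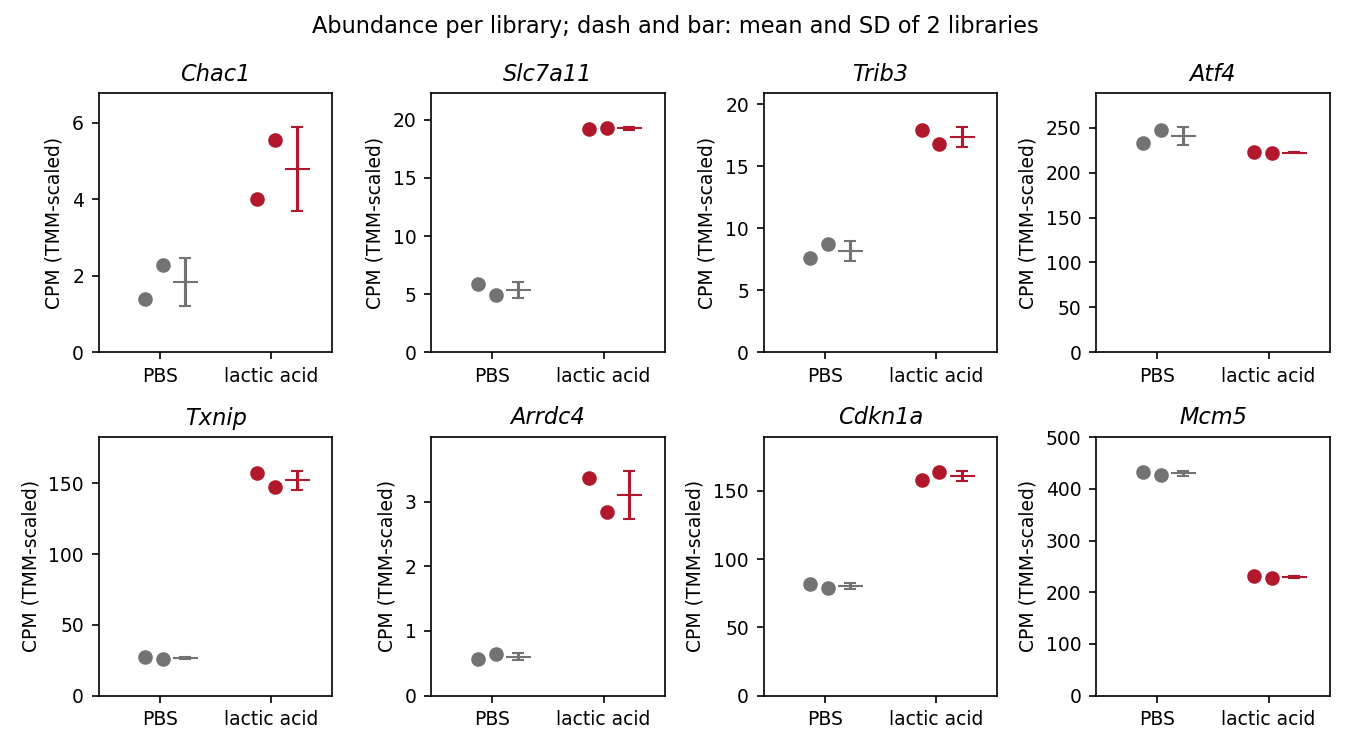
Abundance in CPM (TMM-scaled, y axis from 0) of 8 genes in each PBS library (grey points) and each lactic acid library (red points), with the mean (dash) and SD (bar) of the 2 libraries beside them. Chac1, Slc7a11, Trib3, Txnip, Arrdc4 and Cdkn1a are higher and Mcm5 lower with lactic acid in both libraries, whereas Atf4 has a log2 fold change of -0.11.

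Targets of NRF2, the transcription factor of the antioxidant response, rose as a list: 19 of 27 were higher and 2 lower, the same counts adjusted over the list alone (camera adjusted p = 5.08e-04, and adjusted p = 0.289 with an estimated correlation). Blvrb, a biliverdin reductase, rose 3.07-fold, Abcc1, an exporter of glutathione conjugates, 1.96-fold, and Taldo1, an enzyme of the pentose phosphate pathway, 1.88-fold. The glutathione metabolism list, of which 10 genes are in other lists too, held 13 higher and 4 lower genes of 25, the same adjusted over the list alone, and did not pass (camera adjusted p = 0.0890, in a camera range of 0.0402 to 0.501, with 0.0437 without lactic acid replicate 2). The transferase gene Gsta4 rose 2.58-fold, while Gpx1, a glutathione peroxidase of the cytosol, fell from 245 ± 2.72 to 138 ± 3.91 CPM (log2 fold change -0.83). Iron handling genes were 6 higher and 8 lower of 20, the same adjusted over the list alone (camera adjusted p = 0.679). The list had a median log2 fold change of -0.07 and a mean of 0.06. Pcbp2, an iron chaperone, fell by 0.42 and Steap3, an iron reductase, fell by 0.53 on the log2 scale, and Slc25a37, a mitochondrial iron importer with a near-identical copy, rose by 0.48.

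Of 34 genes of S phase and DNA replication, 31 were lower with lactic acid and none was higher in the edgeR test, and the counts were the same adjusted over the list alone. The list fell with a median log2 fold change of -0.42 (camera adjusted p = 6.06e-11, and adjusted p = 0.289 with an estimated correlation). Subunits of the replicative helicase led it: Mcm5 fell from 430 ± 5.21 to 229 ± 2.83 CPM (log2 fold change -0.91, SE 0.03), Mcm3 from 594 ± 1.97 to 337 ± 9.27 CPM (-0.82), and Mcm2 and Mcm4 fell by 0.69 and 0.65 on the log2 scale. Genes of G2 and mitosis went both ways, with 14 higher and 10 lower of 33, the same adjusted over the list alone (camera adjusted p = 0.679). Mki67, a proliferation marker, fell by 0.35 and Top2a, the mitotic topoisomerase, rose by 0.23 on the log2 scale, as did Cenpa, the centromeric histone, by 0.35. Cdc20, an activator of the anaphase-promoting complex, was lower (-0.31), though it overlaps Elovl1 on the other strand.

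Targets of p53 were higher in 20 of 24 cases and lower in 1, and 21 were higher and 1 lower adjusted over the list alone. The list rose with a median log2 fold change of 0.41 (camera adjusted p = 3.30e-06, and adjusted p = 0.289 with an estimated correlation). Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, rose from 80.2 ± 2.03 to 161 ± 3.91 CPM (2.01-fold). Pmaip1, which encodes the BH3-only protein NOXA, rose 3.45-fold, Trp53inp1, a stress protein, 2.20-fold, and Polk, a translesion polymerase, 1.75-fold. Among 22 apoptosis regulators 7 were higher and 6 lower, the same adjusted over the list alone (camera adjusted p = 0.370). Bcl2l1, which protects against apoptosis, and Bcl2l11, which promotes it, rose by 0.45 and 0.38 on the log2 scale, and the pore-forming Bak1 fell by 0.47.

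Ribosome biogenesis genes, which build ribosomal subunits in the nucleolus, were lower in 24 of 29 cases and higher in 1, the same adjusted over the list alone. The list fell (camera adjusted p = 1.17e-06, and adjusted p = 0.289 with an estimated correlation). Utp20, a factor of the small-subunit processome, fell by 0.66 on the log2 scale, and the abundant nucleolar proteins nucleolin and nucleophosmin followed, with Ncl down from 2959 ± 36.7 to 2111 ± 74.8 CPM (-0.49) and Npm1 from 1665 ± 29.4 to 1243 ± 31.9 CPM (-0.42). Bop1 was lower as well (-0.72), with the limit that Mroh1 overlaps it on the other strand. Cytosolic ribosomal protein genes went the other way, with 27 higher and 3 lower of 39 and 28 and 3 adjusted over the list alone. They rose by small amounts, with a median log2 fold change of 0.17 (camera adjusted p = 0.00184, and adjusted p = 0.292 with an estimated correlation). Rpl13, which has no near-identical copy, rose from 2512 ± 39.2 to 3032 ± 33.0 CPM (1.21-fold), Rps16 and Rpl5 rose 1.35-fold and 1.26-fold, and Rplp0 fell by 0.22 on the log2 scale. Near-identical copies, mostly pseudogenes, exist for 24 of the 39, among them Rps16, Rpl5 and Rplp0, so single values of these genes are uncertain.

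**Figure D3:**
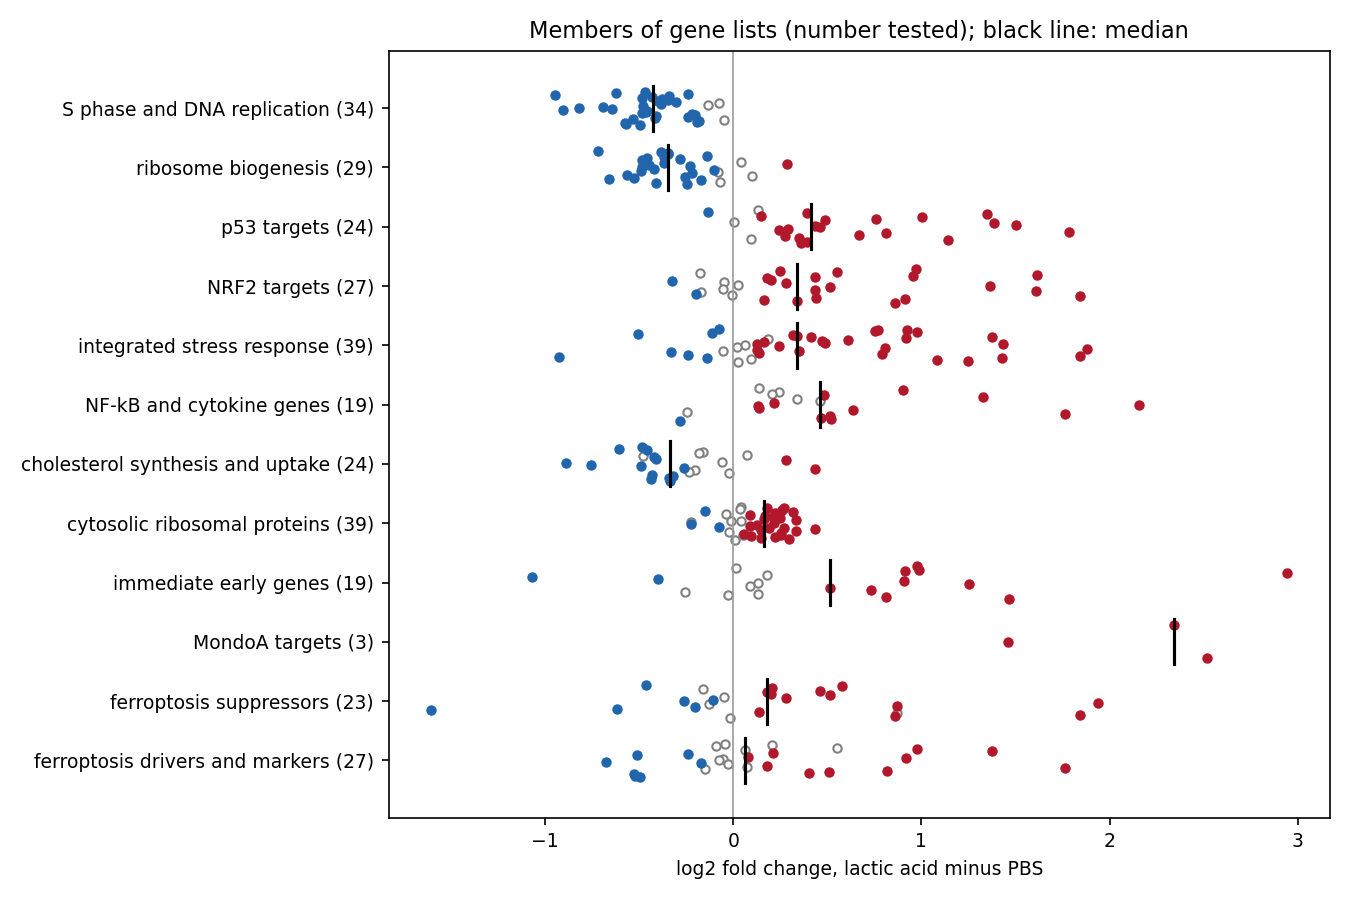
Log2 fold changes (lactic acid minus PBS, x axis) of every tested member of the 10 gene lists past the camera threshold and of both ferroptosis lists, one point per gene, with the number tested in brackets and a black line at the median. Red and blue points are genes higher and lower in the edgeR test and open points did not pass, with medians from -0.42 in S phase to 2.34 in the MondoA targets.

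Genes of cholesterol synthesis and uptake were lower in 14 of 24 cases and higher in 2, the same adjusted over the list alone. The list fell (camera adjusted p = 7.93e-04, and adjusted p = 0.289 with an estimated correlation). Insig1, a sterol sensor, fell by 0.89 on the log2 scale, and Srebf2, the transcription factor that drives the pathway, fell by 0.34. Cyp51, a demethylase of the pathway, was lower (-0.61) and shares its position with Akap9 on the other strand. Fatty acid synthesis genes were lower in 11 of 17 cases and higher in 3, or 11 and 5 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0515, in a camera range of 0.00654 to 0.505). Beside Scd2 and Scd1, Fads2, a desaturase of polyunsaturated fatty acids, fell by 0.93 on the log2 scale. Srebf1, a transcription factor of lipid synthesis, was lower (-0.91), though Rai1 overlaps it on the other strand.

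The 3 listed targets of MondoA, a transcription factor that senses glycolytic intermediates, were all higher, the same adjusted over the list alone. They rose as a list (camera adjusted p = 0.00314, and adjusted p = 0.289 with an estimated correlation). Beside Txnip, Arrdc4, a related arrestin, rose from 0.604 ± 0.0529 to 3.10 ± 0.373 CPM (log2 fold change 2.34, SE 0.39), on 9 and 11 counts with PBS and 53 and 47 with lactic acid. Klf10, a transcription factor, rose 2.76-fold. Genes of glycolysis and lactate transport were 4 higher and 11 lower of 23, or 4 and 12 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.192). Ldha, the lactate dehydrogenase subunit that favours lactate formation, fell from 2254 ± 4.12 to 1843 ± 6.97 CPM (log2 fold change -0.29). Slc16a1, the lactate transporter MCT1, fell from 319 ± 1.02 to 221 ± 5.05 CPM (-0.53). Pkm and Eno1, which have near-identical copies, fell by 0.32 and 0.31 on the log2 scale, and Pdk1, a kinase that inhibits the pyruvate dehydrogenase complex, rose by 0.49. Slc16a3, the transporter MCT4, gave 37.3 ± 4.35 and 34.2 ± 0.373 CPM (log2 fold change 0.12, edgeR adjusted p = 0.202). Without lactic acid replicate 2 it passed (edgeR adjusted p = 0.0380, in a range of 0.0380 to 0.998). Ldhb, the subunit that favours lactate use, which has a near-identical copy, gave 5.57 ± 0.152 and 4.48 ± 0.272 CPM (0.31, edgeR adjusted p = 0.209).

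Hypoxia-inducible genes were 7 higher and 11 lower of 23, the same adjusted over the list alone, and did not pass (camera adjusted p = 0.197). Vegfa, the angiogenic growth factor, rose 1.56-fold and Mxi1, a Myc antagonist, 1.43-fold, while Slc2a1, the glucose transporter, fell by 0.45 on the log2 scale. With the genes of other lists left out, the hypoxia list was lower (camera adjusted p = 0.0319, the lowest of a camera range up to 0.430), and not with an estimated correlation as well (adjusted p = 0.354). Genes of the TCA cycle were 10 higher and 6 lower of 26, the same adjusted over the list alone (camera adjusted p = 0.679). That list had a median log2 fold change of -0.01, which turned to 0.01 with upper-quartile scaling, and a mean of 0.05. Pck2, which makes phosphoenolpyruvate in mitochondria, rose 1.57-fold, Idh2 1.36-fold and Dlat, of the pyruvate dehydrogenase complex, 1.17-fold, as did Suclg2, which has a copy, by 1.21-fold. Nuclear genes of oxidative phosphorylation were 5 higher and 18 lower of 38, or 6 and 18 adjusted over the list alone, and did not pass (camera adjusted p = 0.0515, in a camera range of 0.0390 to 0.479, with 0.0417 without PBS replicate 2). The ATP synthase genes Atp5b, Atp5a1 and Atp5h fell by 0.27, 0.21 and 0.40 on the log2 scale, and Ndufb3 of complex I rose 1.49-fold. Of 12 protein genes of the mitochondrial genome 3 were higher and 4 lower, the same adjusted over the list alone (camera adjusted p = 0.278). The cytochrome b gene mt-Cytb fell from 4364 ± 66.5 to 3051 ± 20.1 CPM (-0.52), mt-Nd2 and mt-Nd4 fell by 0.26 and 0.16 on the log2 scale, and mt-Co1 rose from 9493 ± 25.2 to 12078 ± 22.0 CPM (0.35). Of the 12, 6 have near-identical copies, mt-Co1 and mt-Nd4 among them.

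Cytokine genes and targets of NF-kB were higher in 12 of 19 cases and lower in 1, the same adjusted over the list alone. The list rose (camera adjusted p = 7.93e-04, and adjusted p = 0.289 with an estimated correlation). Beside Lif and Ptgs2, the chemokine genes Ccl2, which attracts monocytes, and Cxcl1, which attracts neutrophils, rose from 128 ± 7.26 to 238 ± 3.43 CPM (1.87-fold) and from 37.0 ± 1.38 to 92.8 ± 1.2 CPM (2.51-fold). Immediate early genes, which respond first to growth factors and stress, were 10 higher and 2 lower of 19, the same adjusted over the list alone. They rose as a list (camera adjusted p = 0.00260, and adjusted p = 0.289 with an estimated correlation). Ier3 rose 2.39-fold, Myc from 332 ± 1.76 to 583 ± 6.63 CPM (1.76-fold), and Dusp6, a phosphatase of ERK, and Fosl1, an AP-1 subunit with a near-identical copy, 1.88-fold each.

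Genes of MHC class I presentation were 8 higher and 2 lower of 13, the same adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0515, in a camera range of 0.0201 without lactic acid replicate 2 to 0.384). H2-K1, a class I heavy chain, rose 2.21-fold, Tap1, a peptide transporter, 2.41-fold, B2m, the light chain, 1.3-fold and H2-D1, another heavy chain, 1.2-fold. Cd274, which encodes the checkpoint ligand PD-L1, measured 3.97 ± 0.317 and 2.58 ± 0.354 CPM (log2 fold change 0.62, edgeR adjusted p = 0.0448). Its call was lost in 8 of 15 alternatives, among them the fits without PBS replicate 2 (edgeR adjusted p = 0.218), without lactic acid replicate 1 (0.197) and without lactic acid replicate 2 (0.0740), in a range of 0.0386 to 0.218. Of 32 interferon-stimulated genes listed, 18 were tested, and 4 were higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 0.679). Bst2, an antiviral membrane protein, rose 2.28-fold, Samd9l fell by 1.1 on the log2 scale, and Rtp4, with 4 to 30 counts a library and overlapping Masp1 and, on its own strand, Gm45338, was higher (2.26). Stat2, a signal transducer of interferons, was higher (0.38, edgeR adjusted p = 0.00575), which was lost without lactic acid replicate 1 (0.0512) and with DESeq2 (0.0784, the highest of a range from 0.00397).

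Genes of the extracellular matrix and of mesenchymal cells were 15 higher and 10 lower of 31, the same adjusted over the list alone (camera adjusted p = 0.257). Their median log2 fold change was 0.04 and their mean 0.43, and 8 were higher and 2 lower by at least 2-fold. Fn1, which encodes fibronectin, rose from 1319 ± 18.8 to 1999 ± 4.69 CPM (1.52-fold) and Cyr61, a target of YAP, 2.51-fold, whereas the collagen gene Col3a1 fell from 977 ± 10.1 to 412 ± 12.5 CPM (log2 fold change -1.25). Lysosome and autophagy genes were 8 higher and 12 lower of 29, the same adjusted over the list alone (camera adjusted p = 0.197). Gpnmb, a glycoprotein of lysosomes and melanosomes, fell from 456 ± 4.28 to 229 ± 5.17 CPM (-1.0), Lamp1, a lysosomal membrane protein, fell by 0.82 on the log2 scale, and Wipi1, an autophagy gene, rose 1.53-fold. Ctsa, a protease of lysosomes, was lower (-0.58), with Pltp overlapping it. Heat shock genes were 5 higher and 11 lower of 18, or 5 and 12 adjusted over the list alone, and did not pass (camera adjusted p = 0.197, direction down). The list's median log2 fold change was -0.17 and its mean 0.47. Its constitutive members Hsp90ab1 and Hspa8 fell by 0.28 and 0.42 on the log2 scale, Dnaja1, which overlaps Smu1, was lower (-0.57), both Hspa8 and Dnaja1 having near-identical copies, and the inducible Hspa1b rose 3.64-fold, though its sequence is nearly that of Hspa1a.

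Genes of pH regulation and of proton or lactate sensing were 4 higher and 4 lower of 17, the same adjusted over the list alone (camera adjusted p = 0.650, direction down, median log2 fold change -0.04 and mean 0.09). Slc4a7, a bicarbonate importer, rose 1.56-fold and Bsg, the chaperone of lactate transporters, fell by 0.21 on the log2 scale. Slc4a2, an anion exchanger, was lower (-0.93), and it overlaps Fastk. No count was recorded for the proton sensor Gpr65 or for the lactate receptor Hcar1 in any library, which allows up to 0.175 to 0.190 CPM in a library (3 counts, counting error only).

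No lymphocyte marker was abundant enough to test, the highest being Cd79a with 10 counts over the 4 libraries, and of the endothelial markers Egfl7 alone was tested (842 counts). Of 3 myeloid markers tested, Cd68 and Cd14 rose 1.85-fold and 1.47-fold to 7.30 ± 0.791 and 14.2 ± 0.986 CPM, and Lyz2 was at 2.10 ± 0.363 against 2.40 ± 0.259 CPM (camera adjusted p = 0.248). Of 6 fibroblast markers, 1 was higher and 3 lower: Pdgfra rose 1.56-fold, Pdgfrb and Col3a1 fell by 1.01 and 1.25 on the log2 scale, and Col1a2 measured 0.493 ± 0.158 against 2.05 ± 0.403 CPM (camera adjusted p = 0.115, in a camera range of 0.0106 to 0.677, with 0.0456 without lactic acid replicate 2). The Col1a2 call was lost on log2(FPKM + 1), at an adjusted p of 0.101 by limma in a range of 5.93e-05 to 0.101. Of 3 lung epithelial markers Krt8, which has a near-identical copy, fell by 1.14, Krt18 was at 99.1 ± 0.986 against 99.3 ± 3.07 CPM, and Krt19 at 0.334 ± 0.382 against 0.762 ± 0.170 CPM (camera adjusted p = 0.197). Krt19 passed without lactic acid replicate 2 (edgeR adjusted p = 0.0159, in a range of 0.0159 to 0.751). For these 3 marker lists the counts were the same adjusted over the list alone. The most abundant genes were mt-Co1, Eef1a1, Hsp90ab1, Eef2 and mt-Cytb. Of the elongation factors, Eef2 rose from 4337 ± 30.2 to 4908 ± 3.85 CPM (0.18), and Eef1a1, which has a near-identical copy, was at 10189 ± 11.5 against 10730 ± 151 CPM (log2 fold change -0.07, edgeR adjusted p = 1.01e-06), which did not pass on FPKM (limma adjusted p = 0.131, the highest of a range from 6.68e-14).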

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

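Removing a GC trend, leaving out genes with near-identical copies, and the estimated correlation without shared genes were tests chosen after the data were seen; the others were fixed before. Chac1 stayed higher and past the threshold in all 15 alternatives, with log2 fold changes of 0.88 to 1.78 and adjusted p from 2.20e-06 to 0.0158; its lowest fold change is on log2(FPKM + 1), which compresses low values. Leaving out 1 library gave 1.07 to 1.78 for Chac1, 5745 to 6110 changed genes in all, 2819 to 3066 higher, 2919 to 3081 lower, and 10 to 13 lists; the lone library of a group was then assumed to vary like the pair of the other. Requiring an absolute log2 fold change of at least 1 left 863 genes (635 higher, 228 lower), and testing against a fold of 1.2 with glmTreat left 2913 (1705 higher, 1208 lower), both stricter by construction. The DESeq2 Wald test called 2251 genes higher, against 3445 by edgeR, and 4745 in all, of which 4737 were shared with edgeR; the cause was not tested. Scaling, filtering and limma-voom gave 6650 to 6854 changed genes, and no gene called both there or in another alternative and by edgeR had opposite signs. Apart from the stricter settings of size, the share of calls that were higher lay between 47.0% and 53.9%. In these alternatives the median log2 fold change of all genes lay between -0.0078 with the GC trend removed and 0.0264 with upper-quartile scaling. Each scaling thus keeps the typical gene near no change, so the near-even split is no evidence of a balanced response.

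Of 10 lists past the threshold, 0 passed camera with an estimated correlation, with or without genes of other lists (4 and 3 at an unadjusted p below 0.05), a test that passed 0 of 20 shifted lists in the simulation, where the preset correlation passed 20 and also 2 of 20 unshifted ones, and 27 of 32 passed fry, which does not compare a list with other genes. In the remaining alternatives each of the 10 kept its direction and its call, and MHC class I presentation, oxidative phosphorylation, fatty acid synthesis, glutathione metabolism, hypoxia and fibroblast markers passed camera in some. Of 143 named genes, 133 kept their call (higher, lower or none) in every alternative that gave a value; among the other 10 are Atf3, Atf4, Cd274, Col1a2, Eef1a1, Gpx4, Krt19, Slc16a3 and Stat2.

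The groups share replicate numbers, and the replicate number as a block gave 6852 changed genes (3459 higher, 3393 lower), 10 lists and a Chac1 change of 1.39. Deviations of same-numbered libraries from their group means correlated at 0.03 across 5864 genes, so no strong effect shared by equal numbers was seen. Whether same-numbered libraries were made together cannot be told from this value, and the labels do not say. Depth limits the genes of few reads: at 22 to 92 reads a library, the size of the Chac1 change is known less well than its direction.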

Other observations

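The gene families and single genes of the next sentences, and the tests of duplicate libraries, of a shared culture, of sums over copies and of a library that stands apart, were chosen after the results were seen, as was setting the planned fits without shared genes or single libraries against the stress response pattern. Genes were grouped by the stem of their symbol into 66 families of at least 15 tested genes without near-identical copies. DEAD-box RNA helicases (Ddx), which unwind RNA in splicing and ribosome assembly, were lower in 20 of 30 cases and higher in 1 (median log2 fold change -0.23, camera adjusted p = 1.48e-04). Subunits of Integrator (Ints), a complex that terminates RNA polymerase II at snRNA and other genes, were lower in 12 of 15 cases and higher in 1 (median -0.30, camera adjusted p = 0.00334). Large-subunit ribosomal protein genes and paralogs (Rpl) without copies were higher in 14 of 16 cases and lower in 1 (median 0.23, camera adjusted p = 0.0180), whereas symbols beginning with Rps, which include S6 kinase genes such as Rps6ka4, were higher in 9 of 28 and lower in 7 (median 0.05, camera adjusted p = 0.652). Symbols beginning with Eif, the stem of translation initiation factor genes and of some of their regulators, were lower in 23 of 43 cases and higher in 7 (median -0.14, camera adjusted p = 0.0305). Symbols beginning with Atp were lower in 23 of 54 and higher in 9 (median -0.17, camera adjusted p = 0.0305). Kelch-like genes (Klhl), many of them ubiquitin ligase adaptors, were higher in 10 of 22 and lower in 2 (median 0.22, camera adjusted p = 0.0461). None of the 6 families past the threshold passed camera with an estimated correlation (adjusted p = 0.529), the form that had little power in the simulation.

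Single genes of secreted metalloproteinases rose: Mmp10 from 0.674 ± 0.294 to 10.2 ± 0.539 CPM, Mmp9 from 0.546 ± 0.0296 to 4.56 ± 0.381 CPM, Mmp13 from 0.607 ± 0.0329 to 5.25 ± 1.04 CPM and Mmp3 from 36.0 ± 0.151 to 72.5 ± 2.94 CPM (SD, 2 libraries each). Mt1 and Mt2, which encode metallothioneins, fell, Mt1 from 260 ± 9.93 to 107 ± 2.95 CPM and Mt2 from 13.5 ± 0.938 to 4.82 ± 0.441 CPM. Polr2a, the largest subunit of RNA polymerase II, fell from 751 ± 5.45 to 371 ± 2.57 CPM and Hexim1, an inhibitor of the elongation factor P-TEFb, from 154 ± 3.03 to 64.7 ± 0.85 CPM. Egr1, an immediate early transcription factor, rose from 0.888 ± 0.348 to 6.82 ± 0.33 CPM, whereas Fos fell from 5.38 ± 0.566 to 2.56 ± 0.741 CPM. The adjusted p of these genes was between 4.53e-38 for Polr2a and 1.92e-04 for Fos (edgeR quasi-likelihood, Benjamini-Hochberg). Of 344 long intergenic non-coding RNA genes tested, 64 were higher and 26 lower.

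The share of genes past the threshold, 49.0%, is large for 2 libraries a group. Libraries deposited under 2 names are argued against, because replicates differed by a mean chi-square per gene of at least 1.81 (SE 0.03) among genes without copies, where counting error alone gives about 1. A GC bias between the groups is argued against as well, since 6845 genes were called after the GC trend was removed. What stays open is whether the replicates share a culture: the biological coefficient of variation was 3.69%, and technical and biological spread cannot be told apart without knowing how the replicates were made. A broad response to lactic acid, through lactate, acidity or both, remains a biological hypothesis, and p-values may be too small if the cultures were shared.

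At 50 genes the libraries of a group differed far beyond counting error (chi-square above 50), 34 in the PBS pair and 21 in the lactic acid pair. Near-identical copies exist for 64.0% of the 50 genes (exact 95% interval 49.2% to 77.1%) against 7.71% of all genes tested (Fisher's exact test, two-sided, p = 7.25e-24). This comparison was not matched for abundance, although the chi-square grows with read count and genes with copies held 14.6% to 14.9% of the counts. Sums over a gene and its copies no longer differed so in 19 of 37 cases (51.4%), such as Rpl17 with lactic acid (8782 and 3013 reads, 13099 and 13695 with copies), and still did in 18, such as Sumo2 with PBS (736 and 2170 with its copy) and Ppia with lactic acid (18657 and 23119 with copies). A gene and its copy can both be among the 37 cases and the 50 genes, as Rpl17 and Rpl17-ps10 are. These counts are therefore not of independent families. Reads moved between copies are thus a candidate explanation for part of the pattern. At genes such as Sumo2 the sums argue against moves among the annotated copies found here as the whole cause. Reads at other copies, or left out as mapping to several places, would not show in the sums. For genes such as Sumo2 and for the 36.0% without a copy (22.9% to 50.8%), among them Actb and Malat1 in the PBS pair, it stays open whether a library stands apart, and no biological explanation was tested.

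The stress response list rose while Atf4 mRNA was slightly lower and Ddit3 did not pass, although Atf4 and CHOP are the factors the list is named for. It stays open whether genes that other lists hold too, such as Slc7a11, carry the rise. Without them 31 genes had a median log2 fold change of 0.24 and passed camera with the preset correlation (p = 0.00319, adjusted p = 0.0105). Camera with an estimated correlation gave p = 0.0782 for them and p = 0.0456 for the full list (adjusted p = 0.289). That form passed 0 of 20 shifted lists in the simulation, so it cannot decide the question. A single library does not account for the rise of Chac1, whose adjusted p was at most 0.00901 with any library left out (edgeR quasi-likelihood, Benjamini-Hochberg, in a range of 2.20e-06 to 0.0158 over all alternatives). ATF4 is known to be controlled at translation, so a change in ATF4 protein without one in its mRNA stays among the open explanations, which RNA counts cannot test. NRF2, which shares targets such as Slc7a11 with the list, and p53, which shares targets such as Sesn2, remain hypotheses as further regulators that were not tested. Trp53 mRNA itself was lower (log2 fold change -0.50).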
